A study of Macaca mulatta and Mus musculus with 5 samples.

How the data were processed

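The study measured single-cell gene expression with 10x 3'-end chemistry in meninges of mouse and in meninges and spleen of rhesus macaque. The mouse library pooled hashtag-labelled meningeal cells of animals aged 2, 21 and 48 days, and the macaque libraries, from animals of 4–8 years, were 2 channels from meninges and 2 from spleen. Per the labels' protocols the sort is given as CD45–CD11b– in mouse and CD45–CD11b–CD3– in macaque, and 30000 mouse or 8000 macaque cells were loaded per channel. The deposited files hold raw UMI counts per gene and cell barcode, which the authors made with Cell Ranger per the submitters' processing notes. Those notes name the build mm10 for all libraries. The macaque tables carry macaque gene identifiers, and the macaque reference is not given in the sources used here.

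The mouse table held 13947 barcodes with 128.09 M UMIs (median 6309 per cell). The meninges channels held 4073 and 4313 barcodes with 19.02 and 19.76 M UMIs (medians 4096 and 4034), and the spleen channels 5840 and 6786 barcodes with 20.11 and 21.99 M UMIs (medians 2397 and 2665.5). Each macaque table lists only genes seen in at least 3 cells, so a gene missing from a table was counted as 0 and, where it is named, is said to be not listed. The genes CD79A, IGLL1 and IGHD were not in the macaque tables. In a simulation from the fitted means and dispersions, with 200 changed genes, 2-fold changes were recovered in 66% of cases over all cells, 72% in mature B-like, 66% in NK-like, 40% in germinal centre B-like, 32% in plasma-like and 38% in innate lymphoid-like cells. In the same simulations 141, 160, 137, 105, 88 and 91 genes were called, of which 0, 14, 9, 0, 3 and 6 were unchanged genes. The tests of the data called 7235, 806, 3196, 66, 453 and 437 genes in the same order. With numbers of changed genes other than 200, these simulated rates need not hold for the data.

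Cells with at least 300 detected genes and at most 10% mitochondrial UMIs were kept, using Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0. Scrublet, run per library within scanpy, removed 39 cells from each meninges channel and 173 from the mouse library. It marked no cell in spleen, where 5839 and 6783 cells passed the filter, so it was taken not to have worked there and the spleen cells were kept. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes were taken, without immunoglobulin, T cell receptor, ribosomal, mitochondrial and cell cycle genes and without list members that are not cell type markers. From these, 30 principal components, 15 neighbours and Leiden clusters at resolution 1 (igraph 0.11.9, seed 0) were computed, without batch integration, for the macaque channels together and for the mouse library alone. Plots were drawn with matplotlib 3.10.9. The pattern for ribosomal genes first also caught the RPS6K kinase genes. It was corrected to ribosomal protein genes after results had been seen, and the first version is given among the alternatives.

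Clusters were named from marker lists of 19 classes. A class needed at least 3 detected markers, a mean score of at least 0.3 and a lead of 0.25 over the next class, except between early and immature B. A cluster stayed unnamed where these failed, where another class had more markers among the 10 leading genes, where its UMIs were under 0.333 of the sample median without an own marker among those genes, or where an NK or innate lymphoid name met T cell receptor genes among them. These thresholds were set after the data were seen. The T cell receptor rule matched mouse gene symbols only, so it could not act in macaque. Macaque clusters named NK or innate lymphoid also hold cells with T cell receptor genes, and the names were left as the rule gave them. The lists of markers, the 23 gene lists, the tests, the rule for named genes and most alternatives were chosen before the data were examined.

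UMI counts were summed per macaque channel over all cells, and over each class with at least 50 cells in every channel, which 5 classes reached. Sums were tested between tissues with edgeR 4.0.16 in R 4.3.3 (trimmed-mean normalization, filterByExpr, quasi-likelihood test, Benjamini-Hochberg adjustment over the genes tested, threshold 0.05). Gene lists with at least 3 measured members were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the lists. The list of immunoglobulin heavy chain constant regions had fewer measured members in macaque and was not tested. List members were also counted with p-values adjusted over the list alone. The differences between tissues were compared between classes with an interaction term on the class sums, with the channel as a block. Genes named in the text are the 12 largest rises and 12 largest falls past the threshold with a mean log2 CPM of at least 5, channels of the tissues apart and a gene symbol, the 4 members of each list with the lowest adjusted p, and the stage genes. Immunoglobulin and T cell receptor variable, ribosomal and mitochondrial genes were left out of the largest changes. Results for some genes that this rule picks are not reported here. Cluster marker genes, and the mouse genes and clusters described, were chosen after their values were seen.

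Shares of classes were compared between tissues with a two-sided exact permutation test and given with exact Clopper-Pearson 95% intervals. For 17 stage genes, of which 14 were found in the macaque tables, the share of cells with at least 1 UMI was taken after thinning every cell to 1000 UMIs at random, leaving out cells with fewer, and unthinned. NK-like or mature B-like cells served as background for genes they should lack. Mouse levels are UMIs of a list scaled to the total UMIs of the class (CPM), with no test for 1 library.

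The alternatives were DESeq2 1.42.0 and its size factors, no filter on low counts, a replicate block, leaving out each channel, a filter of 500 genes and 5% mitochondrial UMIs, doublets kept, counts thinned to the smallest channel, other Leiden resolutions (0.5 and 2), list genes kept in the clustering, thinning to 500 UMIs and no thinning. Gene tests were rerun for all cells and for mature B-like cells, not for the other classes. Resolution 0.5 was rerun for the genes of mature B-like cells and the shares, while resolution 2 and list genes kept in the clustering were rerun for the shares only, and thinning to 500 UMIs and no thinning for the stage genes only. Further alternatives chosen after seeing the data were genes listed in all tables, clusters left out, added or taken alone, a crossed block and the first ribosomal pattern. The mouse cells could not be assigned to ages or animals from the sources used here, so mouse results by age are not analysed here. The channel numbers were not taken to pair animals, since the labels give them only as numbers.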

Results

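Macaque meninges held early B-lineage-like cells while no spleen cell was given that name, and developing B-like cells made up 54.4% of the single mouse meningeal library in the main setting and 44.2 to 51.4% under the alternatives. The macaque data were 10x channels from meninges and spleen, 2 per tissue, and the mouse data were 1 pooled library. After filtering, the meningeal channels kept 4029 and 4269 cells, the spleen channels 5839 and 6783, and the mouse library 13267. Class names are given as "-like" because they rest on marker genes alone. The p-values measure only the spread between these channels, which may be technical, since the labels do not say whether the channels hold different animals. Exact 95% intervals cover counting error only.

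Early B-lineage-like cells, named by genes of immunoglobulin gene rearrangement and the surrogate light chain, made up 12.4% ± 0.66 (SD, n = 2) of macaque meningeal cells. No spleen cell was given this name, but names are given per cluster, so single such cells within other clusters are not excluded. Mature B-like cells were 14.3% ± 0.18 (SD, n = 2) of meningeal cells and 71.5% ± 2.49 (SD, n = 2) of spleen cells. Under the alternative cell filters and clusterings the channels had 6.54 to 12.6% in meninges and 30.2 to 62.2% in spleen, and with the unnamed B-cell clusters 0 and 7 added the class held 1436 of 4029 and 1566 of 4269 meningeal cells. Germinal centre B-like cells, the stage at which antibody genes mutate, were 2.02% ± 0.02 in meninges and 16.6% ± 1.26 in spleen. NK-like cells showed the opposite order, with 31.4% ± 0.47 in meninges and 8.00% ± 0.49 in spleen, as did innate lymphoid-like cells with 9.17% ± 0.12 and 0.916% ± 0.06. Plasma-like cells, which secrete antibody, had overlapping shares of 2.5% ± 0.31 in meninges and 2.66% ± 0.58 in spleen (two-sided exact permutation test, n = 2, p = 1.0). Macrophage-like cells were 0.798% ± 0.135 of meningeal cells and 0 of the spleen cells kept. At Leiden resolution 0.5 the clusters 7 and 8 of the main clustering merged under the name immature B, and the early B-lineage-like share was 1.86% in meninges and 0 in spleen. There no cell was named innate lymphoid, and NK-like cells were 18.4 and 18.4% of meningeal and 3.03 and 3.49% of spleen cells. In every class but the plasma-like cells the meningeal and spleen channels did not overlap, with a two-sided exact permutation p = 0.333, the smallest that 2 channels against 2 can give.

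**Figure D1:**
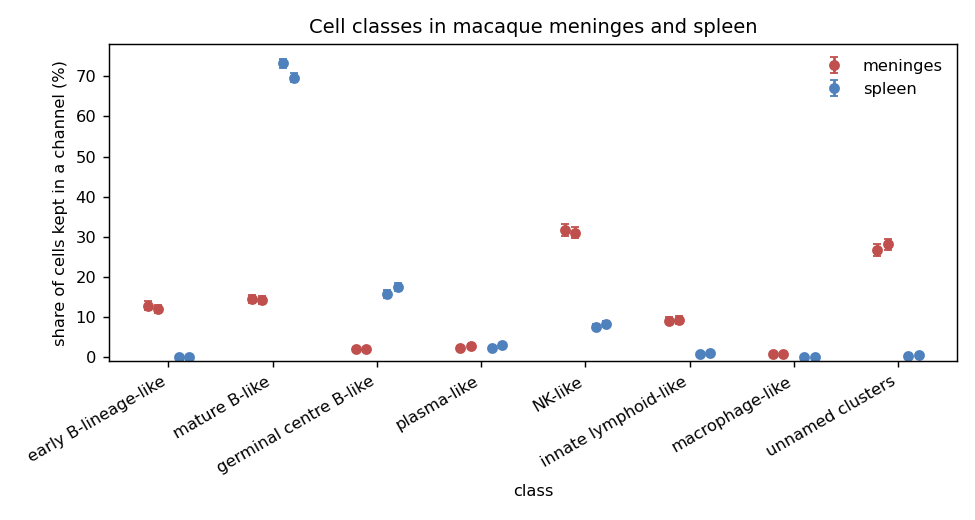
Share of kept cells (%) in each marker-named class for the macaque meninges and spleen channels, with points for single channels and exact 95% binomial intervals as error bars. Early B-lineage-like cells lie at 12.9 and 11.9% in meninges and at 0 in spleen, and mature B-like cells at 14.5 and 14.2% against 73.2 and 69.7%.

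The early B-lineage-like class consisted of 2 clusters. Cluster 8 held 437 and 436 cells, with RAG1 UMIs in 36.2 and 32.3% of them, VPREB3 in 81.9 and 82.8%, IGHM in 100 and 99.8%, and DNTT in 0. Cluster 9 held 81 and 73 cells, with VPREB1 in 81.5 and 83.6%, DNTT in 22.2 and 42.5% and the cycling gene MKI67 in 88.9 and 71.2%. DNTT adds bases at the joints of heavy chain genes in pro-B cells, and VPREB1 encodes part of the surrogate light chain of the pre-B cell receptor. Median UMIs per cell were 2870 and 2866.5 in cluster 8 and 10262 and 10693 in cluster 9, so these unthinned shares are not to be ordered between the clusters. Most mature B-like cells of spleen lay in the low-UMI cluster 14 (37.0 and 21.0% of spleen cells) and in cluster 5, and those of meninges in clusters 1, 5 and 14. Clusters 3 and 10 held most meningeal NK-like cells, while clusters 10 and 11 held those of spleen.

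A further 27.4% ± 0.99 of meningeal cells and 0.398% ± 0.104 of spleen cells (SD, n = 2) stayed unnamed under thresholds set after the data were seen. Cluster 7, marked by NFKBID, EGR2, CCR7 and CD83, held 12.5 and 13.2% of meningeal cells and 0.051 and 0.118% of spleen cells. Cluster 0, marked by DUSP4, GPR183 and NR4A3, held 8.64 and 9.28% against 0.017 and 0.044%. Both are B-cell clusters by MS4A1, found in 97.0 and 96.8% of meningeal cells of cluster 7 and 96.3 and 95.7% of cluster 0. Cluster 13, marked by the myeloid genes CFD, G0S2, C5AR1 and AIF1, held 4.62 and 4.85% against 0.137 and 0.103%, and cluster 16, marked by the dendritic cell genes CLEC9A and FCER1A, held 0.918 and 0.796% against 0.12 and 0.206%. The labels give the sort as CD45–CD11b–CD3–, where the dash after CD45 may be a separator and not a minus sign, since unthinned PTPRC UMIs, the gene of CD45, were found in 85.8 and 86.9% of meningeal cells and 87.9 and 85.1% of spleen cells. CD3E UMIs were found in 59.9 and 61.0% of meningeal cells of the NK-like cluster 10, 57.7 and 51.4% of cluster 3 and 42.3 and 41.0% of cluster 11. They were also found in 55.5 and 58.2% of those of the innate lymphoid-like cluster 4, so both classes hold cells with T cell genes.

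With every macaque cell thinned to 1000 UMIs, RAG1, which makes the DNA breaks of V(D)J recombination, was found in 2.68 and 2.03% of meningeal cells and was not listed in the spleen tables. RAG2, its partner, was found in 0.901 and 0.806% of meningeal cells and DNTT in 0.355 and 0.702%, and neither was listed in the spleen tables. NK-like meningeal cells, which should lack these genes, had RAG1 in 0 and 0%, RAG2 in 0 and 0% and DNTT in 0.086 and 0%. VPREB1 was found in 3.25 and 3.12% of meningeal cells and 0.318 and 0.345% of spleen cells, and VPREB3 in 10.7 and 10.7% against 6.82 and 7.58%. In NK-like cells VPREB1 was found in 0.086 and 0% (meninges) and 0 and 0% (spleen), and VPREB3 in 0.086 and 0.254% and in 0 and 2.04%. MS4A1, which encodes the B-cell surface protein CD20, was found in 35.2 and 36.2% of meningeal cells and 80.7 and 80.2% of spleen cells, against a background in NK-like cells of 3.34 and 3.05% and of 14.3 and 16.1%. NKG7, a granule gene of cytotoxic cells, was found in 29.2 and 28.3% of meningeal cells and 7.11 and 7.43% of spleen cells, against 0.595 and 1.58% and against 0.852 and 0.644% in mature B-like cells. CD3E was found in 13 and 11.4% of meningeal cells and 1.96 and 2.67% of spleen cells, against 0 and 0.197% and against 0.203 and 0.029% in mature B-like cells.

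MKI67 was found in 3.22 and 2.78% of meningeal cells and 5.28 and 4.72% of spleen cells. Its shares in NK-like cells were 3.34 and 3.05% and 6.52 and 6.58%. They are no background for this gene, since unthinned MKI67 UMIs were found in 19.6 and 19.0% of meningeal cells of the NK-like cluster 11. IGHM was found in 39.4 and 39.3% against 59.7 and 58.8% of cells, but its level over all cells was 2145 CPM in meninges and 2092 CPM in spleen, so no order is read. JCHAIN likewise had lower shares in meninges (6.50 and 6.79% against 19.0 and 18.3%) and a higher level (1751 against 1306 CPM, not past the threshold). PTPRC shares overlapped. Thinning left out 365 and 425 meningeal cells and 2069 and 1572 spleen cells. The cells used had median UMIs before thinning of 4279 and 4259.5 in meninges and 4290.5 and 3373 in spleen, and the NK-like cells 3844 and 3802 in meninges and 2578 and 2134 in spleen. Unthinned, the shares were 4.49 and 3.94% for RAG1, 2.90 and 2.11% for RAG2, 0.596 and 0.937% for DNTT, 7.57 and 6.54% against 1.32 and 1.27% for VPREB1, 19.8 and 19.8% against 17.8 and 17.9% for VPREB3, and 41.9 and 43.5% against 85.2 and 86.3% for MS4A1.

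**Figure D2:**
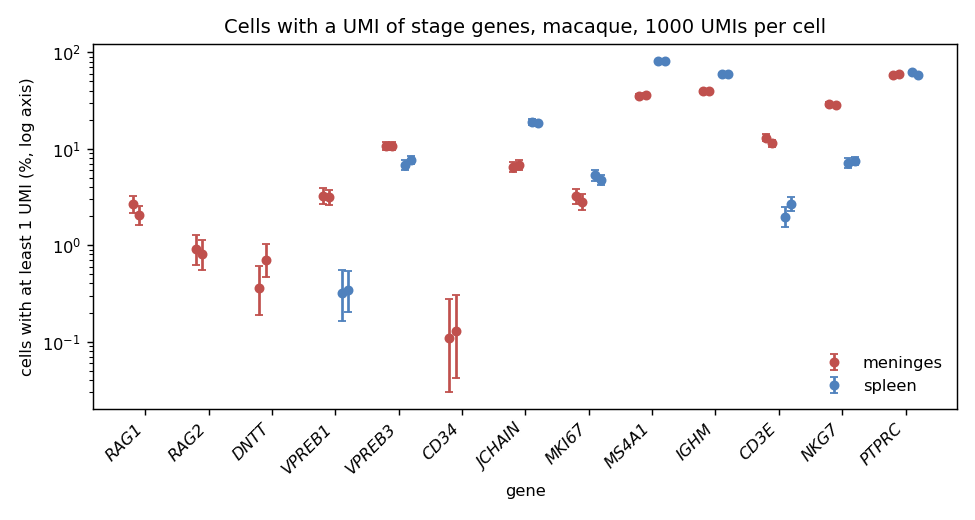
Share of macaque cells (%, log axis) with at least 1 UMI of stage genes after thinning to 1000 UMIs per cell, with points for single channels and exact 95% binomial intervals as error bars. RAG1, RAG2, DNTT and CD34 have points in meninges only, with RAG1 at 2.68 and 2.03%, while MS4A1 lies at 35.2 and 36.2% in meninges and 80.7 and 80.2% in spleen.

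Summed over all macaque cells, several early B-lineage, myeloid and stress genes were higher in meninges, and several germinal centre and mature B genes were lower. VPREB1 rose by 3.12 ± 0.10 (SE) on the log2 scale, VPREB3 by 0.60 ± 0.06, and RAG1 reached 20.1 CPM in meninges against 0 in spleen, where it was not listed. VPREB3 and VPREB1 were not limited to early stages. Unthinned, they were found in 38.7 and 37.9% and in 6.43 and 5.17% of spleen cells of the germinal centre B-like cluster 2. The germinal centre genes RGS13 (-3.10 ± 0.09), MYBL1 (-2.62 ± 0.10), ELL3 (-2.60 ± 0.07) and LMO2 (-1.63 ± 0.06) fell, as did CR2, the complement receptor of follicular B cells (-2.26 ± 0.07), and MS4A1 (-1.36 ± 0.09). CFD, a complement protease, rose by 6.39 ± 0.11 from 10.6 to 894.1 CPM, and IL1B, an inflammatory cytokine of myeloid cells, rose by 7.01 ± 0.15. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 7235 of 12441 genes differed between the tissues, 3864 higher and 3371 lower in meninges, and 7780 had an unadjusted p under 0.05. These sums follow the mix of cell classes, so the classes were also tested apart.

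Other large rises over all cells were those of RRAD (7.64 ± 0.17), the metallothionein MT1X (7.43 ± 0.31), the stress factor ATF3 (7.03 ± 0.12), FOSL2 (6.93 ± 0.18), KLF4 (6.35 ± 0.12) and NR4A3 (6.26 ± 0.09). G0S2, an inhibitor of fat breakdown, reached 133.4 CPM in meninges and was not listed in the spleen tables. PTGDS (7.84 ± 1.69), IGFBP5 (6.51 ± 1.44) and SFRP2 (83.7 CPM, not listed in spleen), genes known from stromal and leptomeningeal cells, came mainly from meninges channel 1, with 2940, 2534 and 3068 UMIs there and 114, 118 and 43 in channel 2. Further falls were those of CAMK1 (-2.70 ± 0.11), NUGGC (-2.63 ± 0.10), FGD6 (-2.19 ± 0.07), BORCS8 (-2.07 ± 0.06), the cytokine LTA (-2.04 ± 0.09), SYNE2 (-1.99 ± 0.08), the receptor TLR10 (-1.97 ± 0.07), VNN2 (-1.96 ± 0.07) and FAM81A (-1.78 ± 0.08). For every gene with a fitted value here, both meningeal channels lay on one side of both spleen channels.

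The gene lists were fixed beforehand. Of 22 lists tested over all cells, camera with its preset correlation placed 17 past an adjusted p of 0.05, 12 up and 5 down. All 17 calls were lost with an estimated correlation, where 0 lists passed although 8 had an unadjusted p under 0.05, so the adjusted p of each list is given both ways. The losses do not measure correlation alone, since the estimate lay below the preset 0.01 for myeloid (-0.051) and T cell receptor genes (-0.011). With an estimated correlation camera also uses the few residual degrees of freedom of the channels, which limits how low its p can get. Germinal centre genes were lower in 9 of 10 and not past in 1 (median log2 -1.74, adjusted p = 4.68e-09, and adjusted p = 0.126 with an estimated correlation). B-cell receptor signalling genes were lower in 15 of 19 and higher in 2, among them CD22 (-1.66) and BANK1 (-1.50), with adjusted p = 2.91e-09, and adjusted p = 0.0825 with an estimated correlation. Class II antigen presentation genes were lower in 8 of 9 (MAMU-DOA -1.54, adjusted p = 0.000932, and adjusted p = 0.153 with an estimated correlation). Cytotoxic granule genes were higher in 17 of 17 (KLRD1 2.66, KLRB1 2.65, NKG7 2.55, PRF1 2.23, adjusted p = 5.65e-39), T cell receptor genes in 14 of 14 (CD3E 2.87, adjusted p = 8e-13) and myeloid genes in 12 of 12 (C1QC 5.37, C1QB 5.02, adjusted p = 8.81e-22), each with adjusted p = 0.0825 with an estimated correlation. Immediate early genes, which respond to stimulation and to tissue dissociation, were higher in 22 of 22 (median 2.75, adjusted p = 5.91e-52) and tissue retention genes in 11 of 13 with 2 lower (adjusted p = 5.99e-48), each with adjusted p = 0.0825 with an estimated correlation.

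V(D)J recombination genes were split over all cells, with 5 of 11 higher (RAG1, RAG2, DNTT, VPREB1 and VPREB3), 4 lower (DCLRE1C -0.97) and 2 not past. Adjusted over the list alone the counts were 6 and 4, and camera gave adjusted p = 0.0285, but adjusted p = 0.249 with an estimated correlation. That call was also lost without any single channel, at adjusted p = 0.240 and 0.223 without the meningeal and 0.492 and 0.388 without the spleen channels. Heat shock genes were higher in 14 of 15 (HSPH1 2.59, adjusted p = 3.37e-13, and adjusted p = 0.164 with an estimated correlation). NF-kB and cytokine genes were higher in 13 of 18 and lower in 4 (TNFAIP3 3.88, adjusted p = 4.00e-08, and adjusted p = 0.131 with an estimated correlation), and survival genes higher in 12 of 17 and lower in 3 (BCL2A1 2.59, adjusted p = 0.000265, and adjusted p = 0.131 with an estimated correlation). Homing receptor genes were higher in 12 of 20 and lower in 5 (CCR7 2.81, CXCR4 1.71, adjusted p = 0.000383). Glycolysis genes were higher in 12 of 19 and lower in 1 (SLC2A3 1.89, adjusted p = 0.00546). Vascular and stromal genes were higher in 10 of 11 (IGFBP7 4.41, EGFL7 3.30, adjusted p = 0.000502). The homing receptor, glycolysis and vascular lists each had camera adjusted p = 0.249 with an estimated correlation. IGFBP7 is also a leading gene of the early B-lineage-like cluster 9, so its rise need not come from vascular or stromal cells. Cell cycle genes were lower in 14 of 26 and higher in 5 (CCNB1 -1.76, CENPF 1.35, adjusted p = 0.0434), with adjusted p = 0.709 with an estimated correlation, and the call was lost without meninges channel 2 (adjusted p = 0.0624). Ribosomal protein genes were lower in 10 of 63 and higher in 5 (RPL22L1 -0.59, adjusted p = 0.0230, and adjusted p = 0.807 with an estimated correlation).

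The other 5 lists did not pass camera over all cells. Memory and atypical B-cell genes were higher in 4 and lower in 6 (ZEB2 1.58, AIM2 -1.40, adjusted p = 0.821), plasma cell and secretory genes higher in 6 and lower in 4 (IRF4 2.03, PRDM1 1.90, adjusted p = 0.417), and erythroid and platelet genes higher in 3 of 4 (HBA 1.92 ± 0.11, HBB 1.75, adjusted p = 0.0634). Type I interferon genes were higher in 10 and lower in 8 of 24 (OASL 2.82, XAF1 -0.74), with a median of 0.10 above 0 and a camera direction below it (adjusted p = 0.880). Neural and glial genes were higher in 2 and lower in 2 of 5 (MBP 0.53), with a median of -0.24 and a mean of 1.28 (adjusted p = 0.962).

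Within macaque mature B-like cells many immediate early genes were higher in meninges. FOS, a transcription factor gene switched on quickly by many stimuli, rose by 5.34 ± 0.17 (SE, 2 channels per tissue) on the log2 scale, from 35.5 CPM in spleen to 1439 CPM in meninges (edgeR adjusted p = 1.52e-13). FOSB rose by 4.95 ± 0.10, NR4A2 by 4.49 ± 0.12, DUSP1 by 3.53 ± 0.09 and NR4A1 by 3.21 ± 0.10. RGS1, which restrains chemokine receptor signals and marks tissue-resident lymphocytes, rose by 3.40 ± 0.10, GPR183, which guides B cells within lymphoid tissue, by 1.97 ± 0.10, and CXCR4 by 0.54 ± 0.08. MS4A1 (-0.16 ± 0.10) and IGHM (-0.02 ± 0.09) were not past the threshold. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 806 of 10368 genes differed, 543 higher and 263 lower, of which 209 by more than 2-fold. The count depends on the setting, with 148 genes (91.9% higher) without a filter on low counts, 170 (89.4% higher) at Leiden resolution 0.5, 384 with DESeq2, 1368 with the stricter cell filter and 4448 with clusters 0 and 7 added.

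Further rises in mature B-like cells were those of RGS2 (3.33 ± 0.17), the heat shock genes DNAJB1 (3.27 ± 0.10) and HSPA1B (2.92 ± 0.11), LMNA (2.65 ± 0.13), ZFP36 (2.47 ± 0.09) and KLF6 (2.38 ± 0.09). The falls were smaller. ITGA1, an integrin that binds collagen, fell by 0.75 ± 0.12 on the log2 scale, LUC7L3 by 0.73 ± 0.09, TRNT1 by 0.73 ± 0.16, IFIT3 by 0.72 ± 0.17, NOL9 by 0.69 ± 0.15, NCKAP5 by 0.65 ± 0.15, IKBKB by 0.64 ± 0.13, CCSER1 by 0.64 ± 0.14, USP44 by 0.62 ± 0.14, TTC14 by 0.62 ± 0.10, C13H2orf49 by 0.61 ± 0.13 and the chemokine receptor gene CCR6 by 0.60 ± 0.11. Of these, NOL9, CCSER1 and USP44 were no longer past the threshold without meninges channel 1, at adjusted p = 0.136, 0.122 and 0.0775, and IFIT3 and NCKAP5 without meninges channel 2, at adjusted p = 0.208 and 0.0522. Of all these falls only those of LUC7L3 and TTC14 kept their call under every alternative set beforehand, and ITGA1, TRNT1, IKBKB, C13H2orf49 and CCR6 lost theirs at Leiden resolution 0.5 (adjusted p = 0.173, 0.0997, 0.0691, 0.230 and 0.197), as did the rise of LMNA (adjusted p = 0.196). ITGA1 is also a leading gene of cluster 15, and in that cluster alone its log2 difference was -0.2 (edgeR adjusted p = 0.65). Another mix of mature B-like clusters may thus underlie its fall. The class had 583 and 607 meningeal cells with medians of 4442 and 4382 UMIs. Its 4275 and 4727 spleen cells had medians of 1402 and 2399 UMIs.

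Among the lists in mature B-like cells, camera placed 7 of 20 past the threshold, all up. Immediate early genes were higher in 18 of 21 and not past in 3 (19 adjusted over the list alone, median 2.33, adjusted p = 1.26e-209), and tissue retention genes were higher in 9 of 13 with 1 lower, ITGA1 (median 2.02, adjusted p = 2.46e-86). Both held with an estimated correlation, at adjusted p = 0.0165 and 0.0223. Heat shock genes were higher in 11 of 15 (HSPB1 3.93, HSPH1 1.48, adjusted p = 2.88e-49, and adjusted p = 0.0943 with an estimated correlation). Survival genes were higher in 6 of 16 (PIM3 1.85, PMAIP1 1.69, BCL2A1 1.59, MCL1 0.92, adjusted p = 1.23e-08, and adjusted p = 0.154 with an estimated correlation). NF-kB and cytokine genes were higher in 5 of 16 and lower in 1 (CCL3 1.86, TNFAIP3 1.08, LTA -0.60, adjusted p = 0.000173, and adjusted p = 0.193 with an estimated correlation). Homing receptor genes were higher in 6 of 17 and lower in 1 (GPR183 1.97, KLF2 1.29, CXCR4 0.54, CCR6 -0.60, adjusted p = 0.000199, and adjusted p = 0.205 with an estimated correlation). Cytotoxic granule genes were higher in 3 of 12 (KLRD1 1.30, NKG7 0.84, TYROBP 0.70, adjusted p = 0.0423, and adjusted p = 0.552 with an estimated correlation), and this call was lost without meninges channel 1 or either spleen channel, at adjusted p = 0.0810, 0.0984 and 0.204. In meningeal mature B-like cells these genes reached only 0.0157 of their level in other meningeal cells, so free RNA of those cells stays open as a source.

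The other 13 lists did not pass camera in mature B-like cells. B-cell receptor signalling genes were higher in 1 and lower in 2 of 19 (DAPP1 0.43, CR2 -0.45, CD72 -0.30, adjusted p = 0.295). Class II genes were higher in 1 (IFI30 0.63) and lower in 1 (MAMU-DOA -0.46), and memory and atypical B-cell genes higher in 4 of 11 (ITGAX 0.60, ZEB2 0.46) and lower in 1 (CD84 -0.57). CR2, CD72 and ITGAX are leading genes of the mature B-like clusters 15, 5 and 1. Another mix of these clusters may thus underlie the changes of these genes, which was not tested. Type I interferon genes were lower in 2 of 22 (IFIT3 -0.72, OAS2 -0.59). Cell cycle genes had a median of -0.15 against a camera direction above 0 (adjusted p = 0.800), and ribosomal protein genes a median of -0.05 against a camera direction above 0 (adjusted p = 0.940).

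**Figure D3:**
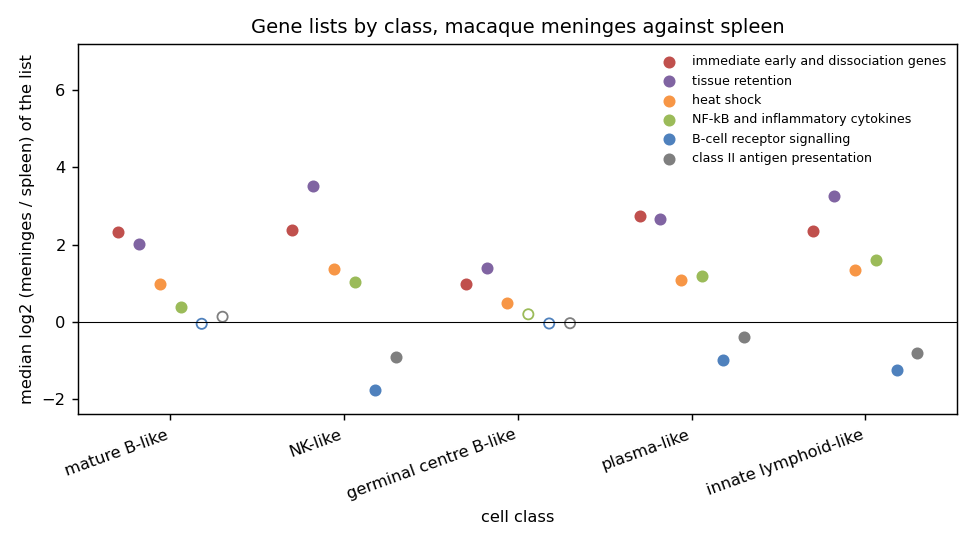
Median log2 difference (meninges minus spleen) of 6 gene lists in each of 5 macaque cell classes, from edgeR fits of 2 channels per tissue, with filled points for a camera adjusted p under 0.05 with the preset correlation and open points otherwise. Immediate early genes lie above 0 in all 5 classes, from 0.97 in germinal centre B-like to 2.73 in plasma-like cells.

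Macaque NK-like cells also had higher immediate early genes and genes of the tissue retention list in meninges, the latter led by CD69, NR4A2, CREM and RGS1. CXCR4, the receptor for the chemokine that holds lymphocytes in marrow and tissue, rose by 3.77 ± 0.08 (SE, 2 channels per tissue) on the log2 scale, CD69, a retention marker, by 3.09 ± 0.08, FOS by 4.83 ± 0.10 and FOSB by 4.94 ± 0.12. The granule genes GZMK (1.23 ± 0.10), CST7 (1.11 ± 0.09) and GZMB (0.63 ± 0.06) and the chemokine gene XCL1 (2.28 ± 0.14) rose as well. RRAD, XCL1 and GZMK are leading genes of cluster 3, which held 461 and 477 meningeal but 10 and 10 spleen cells, so another mix of NK-like clusters may underlie these changes. In cluster 10, CD3E UMIs were found in 59.9 and 61.0% of meningeal and 32.2 and 34.6% of spleen cells, unthinned and at lower depth in spleen. Of 12 T cell receptor genes 5 were higher and 2 lower in the class (camera adjusted p = 0.419). RRAD (8.30 ± 0.32), RGS16 (6.60 ± 0.33), LMNA (5.54 ± 0.27), ATF3 (5.11 ± 0.30) and NR4A1 (5.0 ± 0.30) rose too, while NR4A3 had 190.7 CPM in meninges and 0 in spleen. Of 9306 genes, 1813 were higher and 1383 lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. B-cell genes fell, with IGHM at -2.67 ± 0.23, CD79B at -2.66 ± 0.16, MS4A1 at -2.64 ± 0.10 and BANK1 at -2.09 ± 0.14. NK cells should lack these genes, and 56.6% of the 709 MS4A1 UMIs of spleen NK-like cells lay in 33 cells with at least 5 of them.

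Of 19 lists in NK-like cells 12 passed camera. Tissue retention genes were higher in 11 of 13 (median 3.52, adjusted p = 4.35e-62), immediate early genes in 17 of 19 (median 2.38, adjusted p = 3.09e-52) and heat shock genes in 12 of 13 (median 1.37, adjusted p = 3.34e-25), and B-cell receptor genes were lower in 15 of 18 (median -1.77, adjusted p = 3.58e-13), each with adjusted p = 0.0805 with an estimated correlation. NF-kB genes (10 of 15 higher, 2 lower, adjusted p = 3.47e-12) and class II genes (6 of 8 lower, adjusted p = 5.61e-05) had adjusted p = 0.193 with an estimated correlation. Cytotoxic granule genes (12 of 17 higher, median 0.56, adjusted p = 7.93e-08) and glycolysis genes (10 of 18 higher, adjusted p = 1.28e-05) had adjusted p = 0.124 with an estimated correlation. Ribosomal protein genes were higher in 43 of 63 (median 0.27, adjusted p = 4.68e-09, and adjusted p = 0.351 with an estimated correlation). Survival genes (9 of 13 higher, adjusted p = 5.61e-05), homing receptor genes (7 of 16 higher, 4 lower, adjusted p = 0.000234) and cell cycle genes (5 of 22 higher, 3 lower, adjusted p = 0.0412) had adjusted p = 0.228, 0.149 and 0.619 with an estimated correlation.

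Germinal centre B-like cells differed least, with 59 of 9128 genes higher and 7 lower in meninges by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. FOS rose by 3.40 ± 0.23 (SE, 2 channels per tissue) on the log2 scale, the heat shock gene DNAJB1 by 2.22 ± 0.14, RGS1 by 2.00 ± 0.14, KLF6 by 1.69 ± 0.15 and JUN by 1.64 ± 0.10. MKI67, a gene of dividing cells, rose by 0.54 ± 0.10 and the histone gene H4C3 by 1.08 ± 0.12. BCL6 (0.18 ± 0.12) and RGS13 (-0.19 ± 0.12), genes of this stage, were not past the threshold, so the lower RGS13 over all cells came with fewer germinal centre B-like cells. The named falls were MRPL11 (-0.75 ± 0.15), CD52 (-0.59 ± 0.11), ISG20 (-0.45 ± 0.08) and NME2 (-0.37 ± 0.07). Immediate early genes (8 of 18 higher, adjusted p = 6.68e-46), tissue retention genes (5 of 9, adjusted p = 6.89e-30) and heat shock genes (5 of 14, adjusted p = 3.73e-25) passed camera, each with adjusted p = 0.104 with an estimated correlation. So did cell cycle genes (2 of 26 higher, 13 adjusted over the list alone, adjusted p = 4.19e-10), cytotoxic granule genes (0 of 8 past, adjusted p = 0.0383) and ribosomal protein genes (1 of 63 lower, 32 lower and 5 higher adjusted over the list alone, adjusted p = 6.79e-19), each with adjusted p = 0.386 with an estimated correlation. For those cytotoxic granule genes edgeR gave the 0, and 1199 of all genes tested had an unadjusted p under 0.05.

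Plasma-like cells of meninges had higher immediate early genes and some higher antibody-secretion genes. JCHAIN, which links antibody multimers, rose by 1.24 ± 0.23 (SE, 2 channels per tissue) on the log2 scale, TNFRSF17, the survival receptor of plasma cells, by 1.98 ± 0.23, PRDM1, their master regulator, by 1.17 ± 0.17 and HERPUD1 by 1.26 ± 0.18. ATF3 rose by 8.81 ± 0.42, FOS by 6.18 ± 0.20, KLF6 by 5.74 ± 0.24 and the growth factor gene AREG by 5.90 ± 0.71. The B-cell genes MS4A1 (-3.43 ± 0.86) and CD1C (-2.35 ± 0.56) fell. Unthinned, MS4A1 UMIs were found in 8.70 and 7.76% of meningeal and 25.2 and 38.0% of spleen cells of this class. MKI67 was found in 6.52 and 11.2% against 22.1 and 15.4%. A change within plasma cells can thus not be told apart from another mix of cells in the class. Of 6409 genes 384 were higher and 69 lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, from 92 and 116 meningeal and 131 and 208 spleen cells. Of 17 lists 13 passed camera. Immediate early genes were higher in 14 of 17 (median 2.73, adjusted p = 1.42e-67) and held with an estimated correlation (adjusted p = 0.0464). Tissue retention genes (9 of 10 higher, adjusted p = 2.02e-20) and heat shock genes (9 of 13, adjusted p = 3.53e-17) had adjusted p = 0.0760 with an estimated correlation, and the plasma cell programme (5 of 15 higher, median 0.45, adjusted p = 0.00235) had adjusted p = 0.532 with an estimated correlation. The other 9 calls, such as NF-kB genes (4 of 10 higher, TNFAIP3 3.97), homing receptor genes (8 of 14 higher, KLF2 2.91) and B-cell receptor genes (5 of 16 lower, CD22 -3.70), had adjusted p between 1.47e-07 and 0.0450, and adjusted p between 0.122 and 0.554 with an estimated correlation.

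The class named innate lymphoid-like, whose leading genes include T cell genes and which may hold many T cells, had FOS up by 6.62 ± 0.28 (SE, 2 channels per tissue) on the log2 scale, FOSB by 5.58 ± 0.32, XCL1 by 4.08 ± 0.24 and CD69 by 3.66 ± 0.21. Of 6545 genes 331 were higher and 106 lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, from only 51 and 65 spleen cells. The angiogenic factor VEGFA (89.0 CPM), the checkpoint gene CTLA4 (61.8 CPM) and the chemokine gene CCL20 (57.3 CPM) had 0 UMIs in spleen cells of this class. CD79B (-2.52 ± 0.46), IGHM (-2.52 ± 0.37), MS4A1 (-2.32 ± 0.26) and GIMAP4 (-1.96 ± 0.16) fell. Immediate early genes (15 of 19 higher, median 2.36, adjusted p = 1.55e-71) and tissue retention genes (11 of 13, median 3.25, adjusted p = 4.80e-48) passed camera and both held with an estimated correlation (adjusted p = 0.0343). Of 17 lists 11 passed in all, among them NF-kB genes (6 of 13 higher), B-cell receptor genes (4 of 15 lower) and class II genes (3 of 5 lower), and the 9 other than immediate early and tissue retention genes had adjusted p between 0.0690 and 0.539 with an estimated correlation. Homing receptor genes were among them with a median of -0.01 and a camera direction above 0 (adjusted p = 0.00256, and adjusted p = 0.225 with an estimated correlation).

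In the mouse library, immature B-like cells were the largest class of the main clustering with 48.3% of cells (exact 95% interval 47.4 to 49.1) and early B-lineage-like cells made up 6.13% (5.73 to 6.55). Mature B-like cells were 19.8% (19.1 to 20.5), but 5.32 to 15.9% under the alternatives, and together early and immature B-like cells were 54.4% (53.6 to 55.3). T-like cells were 7.67%, NK-like cells 2.72%, plasmacytoid dendritic-like cells 2.65%, innate lymphoid-like cells 2.51% and macrophage-like cells 0.090%. No cluster was named germinal centre B or plasma cell, which does not exclude single such cells within other clusters. Unnamed clusters held 10.1%, of which cluster 9 (4.10% of all cells, Cd160) had Cd3e UMIs in 97.6% of cells, cluster 16 (3.61%) was marked by Il17a, and cluster 7 (2.41%) by Mcpt8, Mpo, Elane and Cd34. In the early cluster 12, Dntt UMIs were found in 89.2% and Vpreb1 UMIs in 100% of cells, while Rag1 was found in 86.8% of the immature cluster 0, so the markers do not part small pre-B from immature B cells. The immature class also holds the dividing clusters 5, 6, 15 and 18, with Mki67 in 100, 90.4, 100 and 91.0% of cells. Cluster 6 had Vpreb1 in 77.7% and Igll1 in 76.5% of cells, as in dividing pre-B cells, against 10.8 and 10.5% of NK-like cells. Those shares are unthinned, at medians of 19049 and 10021 UMIs. As 1 pooled library of mice aged 2, 21 and 48 days, it gives no test, and the cells could not be assigned to ages.

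**Figure D4:**
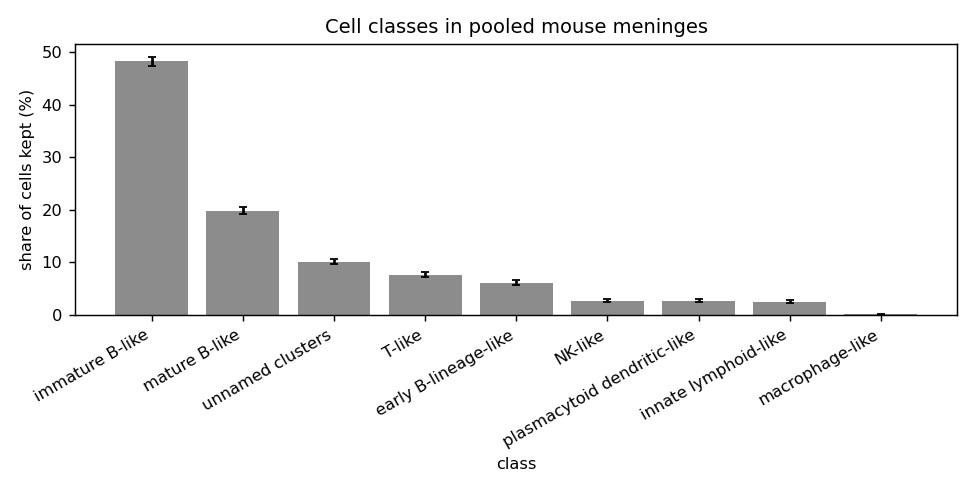
Share of kept cells (%) in each marker-named class of the mouse meningeal library, as bars from 0 with exact 95% binomial intervals. Immature B-like cells reach 48.3%, mature B-like cells 19.8% and early B-lineage-like cells 6.13%.

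The mouse stage genes followed these classes. Thinned to 1000 UMIs per cell, Vpreb3 was found in 65.1% of cells (4.16% in NK-like cells as background), Cd79a in 67.4% (4.43%), Rag1 in 15.6% (0.831%), Vpreb1 in 9.33% (1.39%), Igll1 in 8.12% (0.831%) and Dntt in 5.07% (0.277%). Ms4a1 was found in 20.2% (0.831%) and Ighd, a gene of mature naive B cells, in 9.07% (1.11%). Thinning left out 18 cells, and the median was 6399 UMIs before thinning and 10021 in NK-like cells. Unthinned, Rag1 was found in 37.9% of cells. Dntt reached 1353 CPM in early, 10.8 in immature and 6.51 in mature B-like cells, and Rag1 439.0, 228.5 and 12.2 CPM. V(D)J recombination genes summed to 12679 CPM in early, 4163 in immature and 1510 CPM in mature B-like cells, part of which defines the classes. Class II genes, with which B cells present antigen, ran the other way with 385.4, 831.5 and 16738 CPM, led by Cd74 with 9744 CPM in mature B-like cells.

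Set side by side without a test, the early B-lineage-like share was 6.13% in the mouse library and 12.9 and 11.9% in the macaque meningeal channels. Mature B-like cells were 19.8% in mouse and 14.5 and 14.2% in macaque, and NK-like cells 2.72% in mouse and 31.7 and 31.0% in macaque. The first 2 orders are not stable, since at Leiden resolution 0.5 the early share was 4.94% in mouse and 1.86% in macaque, and the mature share 7.64% in mouse and 9.98 and 9.86% in macaque. The early classes are also not alike in stage. Most macaque cells of that class lay in cluster 8, with RAG1 in 36.2 and 32.3% and DNTT in 0% of cells. The mouse cluster 0, with Rag1 in 86.8% and Dntt in 4.55% of cells, was named immature. The NK-like classes are not alike either, since the macaque clusters 3, 10 and 11 of this class each hold many meningeal cells with CD3E UMIs, while the mouse cluster 9, with Cd3e UMIs in 97.6% of cells, was left unnamed. An immature B-like class held 48.3% of mouse cells and was not named in the main clustering of macaque (at Leiden resolution 0.5 a macaque cluster was). In macaque cluster 8 the early B-lineage score was 1.56 and the immature B score 1.263. The genes CD79A and IGHD, not in the macaque tables, belong to the mature B markers. Germinal centre B-like cells were 2.01 and 2.04% in macaque meninges, and no mouse cluster was named so. The species, the sort (CD45–CD11b– in mouse), the ages (4–8 years in macaque), the marker lists and the number of cells loaded (30000 against 8000) all differed.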

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

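Of the tests below, only that of doublets among spleen NK-like cells was chosen before its result was seen.

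The difference between meninges and spleen was itself not the same in all macaque cell classes, by a test of that difference with edgeR. Against mature B-like cells it differed for 1883 of 10189 genes in NK-like cells, 176 of 10151 in germinal centre B-like cells and 156 of 9047 in plasma-like cells. B-cell receptor genes fell in NK-like cells relative to mature B-like cells (camera adjusted p = 2.07e-11), where this list did not pass (median log2 -0.05, camera adjusted p = 0.295). Tissue retention genes rose further in NK-like than in mature B-like cells (adjusted p = 0.000229), while immediate early genes did not differ past the threshold (adjusted p = 0.767). In germinal centre B-like cells immediate early genes rose less (adjusted p = 1.22e-17) and in plasma-like cells they rose more (adjusted p = 0.000875). These list tests used the preset correlation only. Ribosomal protein genes had the lowest adjusted p of all lists in each pair, with a camera direction above mature B-like cells in NK-like (adjusted p = 7.84e-24) and plasma-like cells (adjusted p = 1.24e-31) and below them in germinal centre B-like cells (adjusted p = 1.94e-18), but in the single classes their calls were lost with an estimated correlation. The channel was a block in these tests.

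FOS was higher in meninges in all 5 tested classes, and the median of the immediate early genes lay above 0 in each. In germinal centre B-like cells only 8 of 18 of them were higher, and the list call was lost with an estimated correlation there (adjusted p = 0.104) and in NK-like cells (adjusted p = 0.0805). Another mix of clusters within mature B-like cells is argued against, since the lowest single-cluster median was 0.721 of that of the whole class (1.57 against 2.18, here as log2 ratios of mean CPM plus 1 and not as edgeR fits). Free RNA of other meningeal cells is argued against as well, since these genes reached 0.772 of their level in other meningeal cells while cytotoxic granule genes reached 0.0157, a ratio of 49.1. Handling of the tissues before sequencing may contribute, since the lowest class median was still 0.968 on the log2 scale and dissociation is known to induce these genes in most cells. A state of the cells in meninges stays open too and was not tested, because the tissue and its handling came together. The tissue retention list was up in the same classes, led in mature B-like cells by NR4A2, RGS1, NR4A1 and RGS2, while ITGA1 fell there. For that list, too, handling and residence in the tissue cannot be told apart.

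Early B-lineage-like cells with RAG1 were found in meninges and not in spleen. Lower depth of the spleen cells is argued against, since after thinning the lower meningeal channel had RAG1 UMIs in 2.03% of cells, against 0.08% that 3 cells of a spleen channel would give. Free RNA is argued against, since after thinning 0% of NK-like cells in both meningeal channels had a RAG1 UMI, with an upper 95% limit of at most 0.315%, against a lower limit of 1.61% over all cells of the lower channel. Marrow or blood carried into the meninges sample cannot be told apart from resident cells, since HBA rose by 1.92 on the log2 scale, MPO and ELANE did not enter the test and the sort may remove CD11b+ cells. A population of early B cells that belongs to the meninges remains a hypothesis that these data leave open.

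B-cell genes such as MS4A1 were lower in meningeal than in spleen NK-like cells. Free RNA of B cells in the spleen suspension may be a source. For 9 mature B markers the median log2 ratio of spleen innate lymphoid-like over NK-like cells was -0.33, with a range from -0.97 to 0.21. Only markers with at least 5 UMIs in the spleen innate lymphoid-like cells were compared, and BANK1 was not among them. Markers low in those cells could thus not enter, which narrows the range. Doublets of NK-like and B cells may be another, since 56.6% of the MS4A1 UMIs of spleen NK-like cells lay in cells with at least 5 of them and no spleen doublet was removed. Both stay open, as does a difference between the NK-like cells of the tissues, which was not tested.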

How the results depend on the processing

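The alternatives that keep only genes listed in all tables or that leave out, add or single out clusters, the crossed block and the first ribosomal pattern were chosen after seeing the data, and the others beforehand.

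Over all macaque cells between 5563 and 7685 genes differed under every alternative run, within 1.5 times of 7235, and all 264 and 70 values of the named genes kept their direction and stayed past the threshold. Leaving out single channels gave 6275 to 7064 genes, where the spread comes from the 2 channels of the other tissue only. Under all alternatives for all cells and mature B-like cells the median log2 difference of all genes lay between -0.034 and 0.03. The 17 list calls over all cells became 0 with an estimated correlation in camera, where 8 lists had an unadjusted p under 0.05. The V(D)J list also lost its call without a filter on low counts and with the replicate block, at adjusted p = 0.398 and 0.234.

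For mature B-like cells the count of 806 genes moved more. It was 384 with DESeq2 (81.8% of them higher in meninges, against 67.4%), 148 without a filter on low counts (91.9% higher), 1368 with the stricter cell filter and 170 at Leiden resolution 0.5 (89.4% higher), and leaving out single channels gave 539 to 1014. Chosen later, the first ribosomal pattern gave 1287 genes and adding the unnamed B-cell clusters 0 and 7 gave 4448. Clusters 1, 14, 15 and 5 alone gave 376, 744, 88 and 228. At Leiden resolution 0.5, 1873 of the 2042 cells of cluster 1 lay in an unnamed cluster, and the class held 402 and 421 meningeal cells. Whether such changes of the class caused these shifts was not tested. Of the named genes in this class 254 values stayed past the threshold and 34 did not under the alternatives set beforehand (the 34 are values of the falls, apart from that of LMNA at Leiden resolution 0.5), and 176 and 33 under those chosen later. The direction reversed for ITGA1 (0.15 in cluster 14 alone) and NCKAP5 (0.03 in cluster 15 alone), both then not past the threshold, and the cause was not tested. The rises of FOS, FOSB, NR4A2, RGS1 and DNAJB1 kept their calls under each of these alternatives. The 7 list calls became 2 with an estimated correlation, which kept immediate early and tissue retention genes, and 11 with clusters 0 and 7 added.

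The channel numbers were not taken to pair animals. A replicate block by channel number gave 7110 and 961 genes for all cells and mature B-like cells, and pairing the channels crosswise gave 7685 and 1325, while the deviations of same-number channels from their tissue means correlated at -0.123 and -0.154 across genes.

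The early B-lineage-like share of macaque meninges was 1.86% at Leiden resolution 0.5, where its cluster 8 merged with the unnamed cluster 7 under the name immature B. There early and immature B-like cells together were 25.3 and 25.0%, against 0.034 and 0.133% in spleen. The early share was 13.8% with the stricter cell filter, 11.0% with list genes kept in the clustering and 11.9 to 12.9% without single channels. It stayed above spleen in each of these settings. With the first ribosomal pattern it was 12.7%. The number of stage genes with both meningeal channels above spleen was 8 under all alternatives run for it. In mouse, early and immature B-like cells together (54.4%) were 45.9 and 44.2% at Leiden resolutions 0.5 and 2, 48.5% with the stricter filter, 51.4% with doublets kept and 48.7% with list genes kept. Early B-lineage-like cells (6.13%) were 4.94, 7.07, 8.20 and 4.23% at those resolutions, with the stricter filter and with list genes kept. Mature B-like cells (19.8%) were 7.64, 12.4, 5.32, 14.5 and 15.9% in the order resolution 0.5, resolution 2, stricter filter, doublets kept and list genes kept, so the border between mouse immature and mature B-like cells depends on the clustering. The stricter filter left 6846 mouse cells. Mouse results by age were not run, since no cell could be assigned to an age. The other classes were tested in the main setting only. With 2 channels per tissue and 200 changed genes, the simulated recovery of 1.5-fold changes was 38% in mature B-like and 2% in plasma-like cells.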

Other observations

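The values here were all looked at only after the data were seen.

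By a chi-square test over cells, the meningeal channels did not differ in cluster sizes beyond counting error (chi-square 11.0 on 18 degrees of freedom, p = 0.894), while the spleen channels did (chi-square 495.4 on 14 degrees of freedom, p = 8.7e-97). Across genes their counts varied 5.34 and 8.69 times as much as counting error alone. The low-UMI cluster 14 of mature B-like cells, marked by FCRL1 and FCMR, held 37.0% of cells in spleen channel 1 and 21.0% in spleen channel 2, with medians of 795 and 736 UMIs.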
